A study of Canis lupus familiaris with 5 samples.

How the data were processed

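The series measured binding of double homeobox transcription factors to dog DNA by chromatin immunoprecipitation and sequencing (ChIP-seq) in an immortalized canine myoblast line. The 5 samples fall into 5 groups of 1 library each: human DUX4, canine DUXC, the canine isoform DUXC-ALT, and 2 luciferase lines, a polyclonal and a monoclonal one. Per the labels' protocols, factors were switched on with doxycycline (1 µg/ml, 24 hours), crosslinking lasted 11 min in 1% formaldehyde, and chromatin was sheared to fragments of 150 to 600 bp. The canine factors carried the C-terminal domain of human DUX4, so that the same rabbit antiserum to that domain could be used for all of them, per the labels. The DUX4 and DUXC lines were monoclonal and the DUXC-ALT line was polyclonal, so clonality differs along with the factor.

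The processed data are 3 peak lists, 1 per factor, each named after a single library, so peaks were taken as called per library. The submitters' processing notes name CASAVA, BWA 0.7.10, MACS2 2.1.0 and the dog genome build canFam3, with no role or order. The authors' lists give the position, summit and width of each peak, its nearest gene and transcript, its place relative to genes, and at most 1 repeat per peak. The column named pileup was read as the signal height at the summit, which its name alone does not state. The deposited fold enrichment was taken as the ratio of that height to the local background of the peak caller, with 1 added to each. The local background was thus (pileup + 1) / fold enrichment − 1. Neither the labels nor the processing notes say which library was the control for each list, what threshold was set or what filters followed, so a fold enrichment is not comparable across lists. The deposited −log10 p-value and −log10 q-value are the caller's own test of each peak, and the smallest −log10 q in the DUX4, DUXC and DUXC-ALT lists was 2.03, 2.03 and 2.08. Fold enrichment and q are the authors' values and were used to describe, rank or filter the peaks of each list, and to correlate overlapping peaks by rank. Cutoffs were the same number in every list and need not be equally strict. Values of several lists given side by side do not rank the factors. Pileup values fell on multiples of 0.917 in the DUX4 list, 1 in the DUXC list and 0.871 in the DUXC-ALT list. In each list 100% of the values up to 40 multiples lay within 0.05 of a whole multiple. The scaling therefore differed between lists, and the number of reads in each library is unknown from these files. A rough relative depth after the caller's scaling was taken as the background floor (percentile 1 of the local background) per bp of the list's shortest peak. It assumes that the shortest peak is as long as the caller's fragment length.

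Peak lists were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance levels came from 1000 random placements of the same peak lengths on the same chromosomes. Placement was uniform along each chromosome, so it did not follow repeats, mappable sequence or open chromatin. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Ratios of median fold enrichment and Spearman correlations across peaks carry 95% percentile bootstrap intervals from 2000 draws over peaks; peaks are not replicates. The overlap code was tested on simulated lists with planted overlaps. In the DUXC on DUX4 comparison (6031 peaks) and in the DUXC-ALT comparisons on DUX4 and on DUXC (561 peaks each), 0 peaks were wrongly classed. Peaks without a planted overlap were placed with the same code that then classed them, so only the planted overlaps were a check. With 1 library per group there is no replicate check on any difference, so no p-value is given.

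Distances to transcription start sites (TSS) were taken from the lists. Random placements were measured against the TSSs of the 21684 genes and 23636 transcripts that the lists name, which leaves out genes nearest to no peak, so that the chance level is a lower estimate. A peak was assigned to a repeat when its summit lay in the repeat recorded for it. A local background was called raised when it exceeded 3 times the list's floor, the percentile 1 of local backgrounds in that list. Gene names are those paired with Ensembl genes in the lists, dog symbols or those of human homologs, and 46.6% of DUX4, 53.2% of DUXC and 50.1% of DUXC-ALT peaks had a named gene. The reference table of dog genes is of another assembly (UU_Cfam_GSD_1.0) and was used for names only.

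Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives except those named below. The 12 lists cover DUX4 target and cleavage-stage genes, double and PRD-class homeobox genes, pluripotency and germline genes, myogenic regulators and satellite cell genes, muscle structural genes, fibroblast genes, neural genes, liver and gut genes, innate immune and interferon genes, apoptosis and p53 pathway genes, nonsense-mediated decay and splicing genes, and housekeeping genes. For each list, genes with a peak within 5 kb of a TSS were counted beside 10000 random lists of the same size from 11509 named genes, matched on gene length decile, and the random range is the central 95% of these lists. A peak counts only for the gene the authors assigned it to, and genes are Ensembl genes, so that copies sharing a symbol, such as those of GAPDH, count separately. Only genes to which some peak list assigned a peak are among the 11509, so listed genes without one were left out of every count. Named genes were, for each peak list, the 10 strongest peaks by fold enrichment in a named gene or within 10 kb of one, 1 peak per gene. To these were added genes of the DUX4 target, homeobox, pluripotency, myogenic and muscle structural lists with a DUXC or DUXC-ALT peak within 5 kb of a TSS, and up to 15 peaks at DUX4 target list genes at any distance. Other genes named in the text, and the repeat families MER21C, MER21B, MLT1D, MLT1A0, L1_Canis1, L1_Cf and SINEC, were chosen after their values were seen.

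Alternatives changed the overlap that counts as shared (50% of both peaks, summits within 100 bp, centred windows of 200 bp), the peaks used (a q-value under 1e-05, fold enrichment of at least 10, equal numbers of the strongest peaks), the chance level (shifts of 10 to 100 kb), the strength measure (−log10 q), the TSS distance (1 or 50 kb), the share of the peak in a repeat and the matching of gene lists. Alternatives added after the data were seen left out peaks of raised local background, left out peaks in MER21C or MER21B copies, kept as many of the strongest DUX4 peaks as there are DUXC peaks, or counted any overlap with the recorded repeat. Motif content was not analysed, for want of a genome sequence of the build. Random placements were not run for repeats, exons and introns, which would need a full annotation of the build. The 2 luciferase libraries were not analysed here.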

Results

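Binding of human DUX4, canine DUXC and the isoform DUXC-ALT was compared in canine myoblasts carrying 1 doxycycline-inducible factor each. The comparison asks how similar the canine proteins are to human DUX4 in where they bind. Per the labels, both canine proteins carried the C-terminal domain of human DUX4, the target of the antiserum used for every factor. What the shared domain and antiserum add to common peaks was not tested. DUX4 is a double homeobox factor of the early embryo whose expression in muscle causes facioscapulohumeral dystrophy. Each factor had 1 ChIP-seq library and 1 peak list on canFam3, and 2 luciferase libraries served as further groups. The DUX4 list held 85825 peaks, the DUXC list 6031 and the DUXC-ALT list 561. All values describe these single libraries, with no replicate check, and the number of reads is unknown from the lists.

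The strongest named DUX4 and DUXC sites coincided at the promoter of PNN, which encodes pinin, a protein of nuclear speckles and cell junctions. The DUX4 peak there (chromosome 8, 17353297 to 17353818, 213 bp upstream of the TSS) had a fold enrichment of 31.6 and the DUXC peak (17353376 to 17353847) of 44.3, and no DUXC-ALT peak overlapped them. The next strongest named DUX4 peaks lay in intron 1 of GNAQ, a G protein subunit gene (31.0, in a MER21C copy), near RAP2A, a small GTPase gene (29.8), in exon 9 of EPRS, a tRNA synthetase gene (29.8), and in intron 21 of MYOM1, which encodes the sarcomere protein myomesin (28.5). They were followed by intron 1 of MARK3 (28.5), the BCL2L2-PABPN1 promoter (27.8), TNFRSF11B, the osteoprotegerin gene (27.7), intron 1 of TMX4 (26.9) and intron 3 of PLEKHA5 (26.6). Of these 10 DUX4 peaks, those at PNN, GNAQ, MARK3, BCL2L2-PABPN1 and PLEKHA5 overlapped a DUXC peak.

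In the DUXC list, PNN was followed by the promoters of BIN2 (24.4) and PCGF1, a Polycomb group gene (24.2; chromosome 17, 48632471 to 48632930), and the TSS of TOP2A, which encodes a DNA topoisomerase (22.4). The DUX4 list had overlapping peaks at BIN2 (18.3), PCGF1 (5.22) and TOP2A (23.3). Further strong DUXC peaks lay in intron 6 of USP37 (21.4), near the complement receptor gene C5AR1 (20.8), in intron 1 of DLG5 (20.6), near the chemokine gene CTACK (20.2), in exon 11 of TBC1D2B (19.9) and in intron 5 of MRPS31 (19.7). Those at USP37, CTACK and TBC1D2B overlapped no DUX4 peak. The strongest named DUXC-ALT peak covered the TSS of RBM14, which encodes an RNA-binding coactivator (17.9; chromosome 18, 50728359 to 50728738). It was followed by HS6ST3, a heparan sulfate sulfotransferase gene (16.0), the promoter of RNF139, a ubiquitin ligase gene (15.8), intron 1 of STIM1, the calcium sensor gene (15.7), intron 1 of SLC39A11, a zinc transporter gene (15.7), and the PCGF1 promoter (14.8). The list went on with GZMK (13.8), intron 1 of the trehalase gene TREH (13.6), the promoter of GTF2F1, a general transcription factor gene (13.6), and intron 2 of MXI1 (12.7). PCGF1 and TREH carried peaks in all 3 lists, and the HS6ST3, GZMK and MXI1 peaks lay in MER21C copies.

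The DUX4 list was 14.2 times as long as the DUXC list, which was 10.8 times as long as the DUXC-ALT list. Median fold enrichment was 7.37 in the DUX4 list (quartiles 5.89 and 9.68), 7.02 in the DUXC list (5.92 and 8.46) and 8.30 in the DUXC-ALT list (7.03 and 9.42). Fold enrichment reached 10 at 19870 DUX4, 766 DUXC and 102 DUXC-ALT peaks. Median peak width was 309 bp, 300 bp and 141 bp in the same order. Raised local background was found at 2.88% of DUX4, 8.34% of DUXC and 9.45% of DUXC-ALT peaks. A rough relative depth after scaling, from the background floor, was 1.47 for DUX4 and 1.62 for DUXC-ALT, with DUXC at 1. Peak numbers depend on depth and calling threshold as well as on binding, so the lengths of the lists do not rank the factors.

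Many DUXC peaks lay at DUX4 sites, among them PNN, BIN2, TOP2A and ZSCAN4. Of the 6031 DUXC peaks, 3361 overlapped a DUX4 peak (55.7%, 95% exact Clopper-Pearson interval 54.5 to 57.0%), 23.1 times the mean of the random placements (2.41%, range 1.84 to 3.03%). In the other direction 3362 DUX4 peaks overlapped a DUXC peak (3.92%, 3.79 to 4.05%; random mean 0.169%). The shared sites were the stronger DUX4 sites: their median fold enrichment was 10.8, against 7.32 at DUX4 peaks without DUXC, a ratio of 1.48 (bootstrap 1.45 to 1.51). Overlap with DUXC rose from 1.57% in the weakest to 10.4% in the strongest of 5 equal groups of DUX4 peaks. In the DUXC list, overlap with DUX4 rose from 45.1% in the weakest to 69.0% in the strongest of 5 equal groups, with a ratio of medians of 1.08 (1.06 to 1.11). Summits of overlapping DUXC and DUX4 peaks were a median of 33 bp apart, and Spearman's rho of fold enrichment across these peaks was 0.296 (bootstrap 0.264 to 0.326). With summits required within 100 bp of each other, the share of DUXC peaks at DUX4 peaks was 49.6%. With the DUX4 list held to as many of its strongest peaks as the DUXC list has, 15.8% of DUXC peaks overlapped it. Between the 561 strongest peaks of each list the share was 8.20%. A shorter DUX4 list has fewer peaks to overlap, so lower shares follow from its construction. No chance level was computed for the cut lists.

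**Figure D1:**
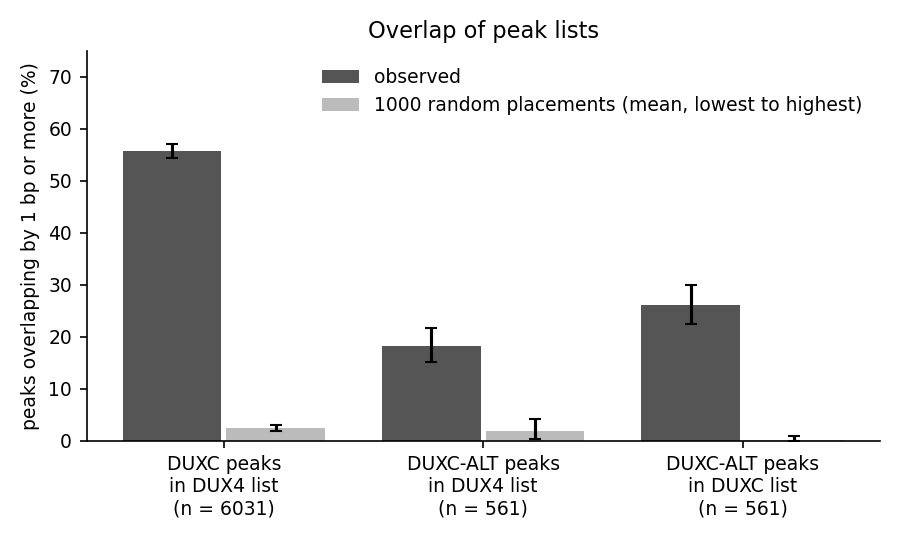
Share of peaks (percent) that overlap a peak of another list by 1 bp or more, for DUXC in DUX4 and DUXC-ALT in DUX4 and in DUXC; dark bars are observed shares with exact 95% intervals and light bars the mean of 1000 random placements with their lowest and highest values. The observed shares of 55.7%, 18.2% and 26.0% lie above every random placement.

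**Figure D2:**
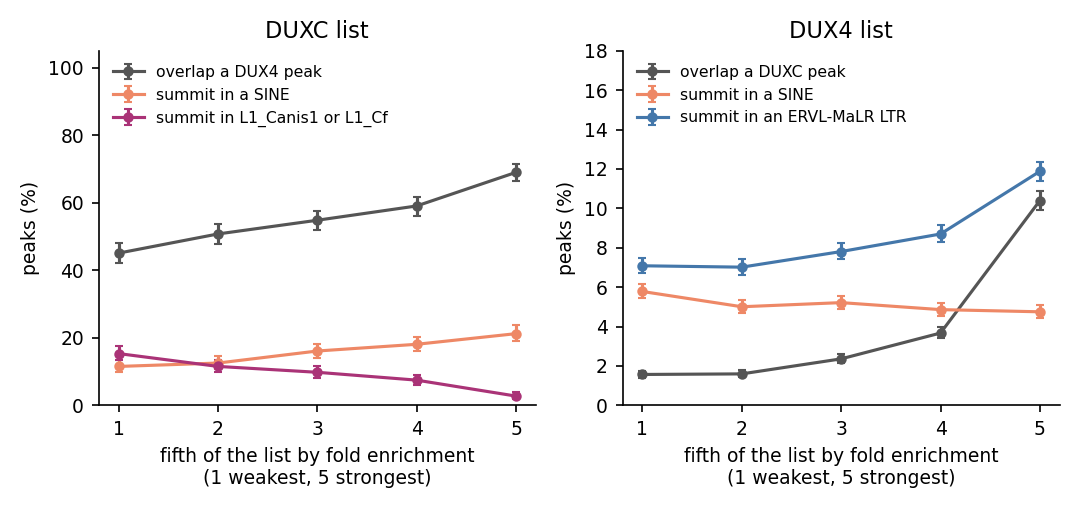
Share of peaks (percent) that overlap the other list, lie in a SINE, or lie in L1_Canis1 or L1_Cf (DUXC) or an ERVL-MaLR LTR (DUX4), in 5 equal groups of the DUXC list (left) and of the DUX4 list (right), ordered by fold enrichment from weakest to strongest, with exact 95% intervals. Overlap between the lists is higher in the strongest group (69.0% and 10.4%) than in the weakest (45.1% and 1.57%).

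DUXC-ALT peaks met the DUX4 list less often than DUXC peaks did. They shared the PCGF1, CTR9 and TREH sites with both other lists and the RBM14, RNF139 and STIM1 sites with DUXC. The DUXC list is far shorter than the DUX4 list, so shares of peaks met in the 2 lists are not comparable. Of 561 DUXC-ALT peaks, 146 overlapped a DUXC peak (26.0%, 22.4 to 29.9%), 191 times the random mean of 0.136% (range 0 to 0.891%). This multiple rests on a very small random mean, and random placement does not follow the repeats that both lists occupy. DUX4 peaks were met by 102 (18.2%, 15.1 to 21.6%), 9.98 times the random mean of 1.82% (0.357 to 4.10%), although the DUX4 list is far longer. Both other lists were met by 44 DUXC-ALT peaks (7.84%), DUXC alone by 102, DUX4 alone by 58 and neither by 357 (63.6%). At the CTR9 promoter, named after its values were seen, the fold enrichment was 12.02 for DUXC-ALT, 11.4 for DUXC and 11.6 for DUX4; CTR9 is part of the PAF1 transcription elongation complex. Shared and unshared DUXC-ALT peaks had similar median fold enrichment, with ratios of 1.04 (1.00 to 1.12) for overlap with DUXC and 1.03 (1.00 to 1.11) for overlap with DUX4. On the DUX4 side, peaks that met DUXC-ALT had a median of 6.68 against 7.37 at the others, a ratio of 0.905 (0.837 to 1.00), and overlap with DUXC-ALT went from 0.151% in the weakest to 0.0757% in the strongest of 5 equal groups of DUX4 peaks (intervals 0.0990 to 0.222% and 0.0403 to 0.129%). Spearman's rho across overlapping peaks was 0.259 (0.0963 to 0.403; 146 pairs) with DUXC and 0.0217 (-0.194 to 0.221; 102 pairs) with DUX4. When 50% of both peaks had to overlap, the DUXC-ALT shares were 10.3% in DUXC and 8.38% in DUX4. Between the 561 strongest peaks of each list they were 4.63% and 0.178%, where shorter lists to overlap again lower the shares by construction.

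DUXC peaks lay near gene starts more often than DUX4 peaks, with promoters of PNN, BIN2, PCGF1 and TOP2A among the strongest. A TSS lay within 5 kb of 16.6% of DUXC peaks (15.7 to 17.5%; random mean 10.0%, range 8.61 to 11.4%), 16.2% of DUXC-ALT peaks (13.3 to 19.5%; 9.83%, 6.24 to 13.5%) and 11.3% of DUX4 peaks (11.1 to 11.5%; 9.77%, 9.40 to 10.1%). Within 1 kb the shares were 4.66% for DUXC (4.14 to 5.22%), 3.03% for DUXC-ALT (1.77 to 4.81%) and 2.27% for DUX4 (2.17 to 2.37%). The DUX4 and DUXC-ALT values at 1 kb lay inside their random ranges, which reached 2.48% and 4.28%. Among DUXC peaks, 3.90% of those shared with DUX4 and 5.62% of those without DUX4 were within 1 kb of a TSS, with intervals of 3.27 to 4.61% and 4.77 to 6.56%. Distal intergenic sequence held 56.7% of DUX4, 52.8% of DUXC and 55.3% of DUXC-ALT peaks, introns 33.2%, 32.6% and 33.9%, and exons 1.83%, 2.01% and 1.07%. The random means rest on an incomplete set of TSSs and are lower estimates.

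The 3 lists differed in the repeats they occupied. Copies of MER21C and MER21B, long terminal repeats (LTRs) of endogenous retroviruses, held the summits of 280 of the 561 DUXC-ALT peaks (49.9%, 45.7 to 54.1%), including those near HS6ST3, GZMK and MXI1. They held 258 DUXC summits (4.28%, 3.78 to 4.82%) and 439 DUX4 summits (0.512%, 0.465 to 0.562%), so the DUX4 list had more such sites in number and a far lower share. Among DUXC-ALT peaks, MER21C or MER21B held 47.3% of those shared with DUXC (38.9 to 55.7%) and 50.8% of the rest (45.9 to 55.8%). SINE copies held the summits of 15.9% of DUXC peaks (14.97 to 16.8%), 5.12% of DUX4 peaks (4.97 to 5.27%) and 1.25% of DUXC-ALT peaks (0.503 to 2.55%). DUXC peaks shared with DUX4 were in SINEs more often than those without (20.0%, 18.7 to 21.4%, against 10.7%, 9.53 to 11.9%). At these shared sites 10.8% of DUX4 summits were in SINEs, while any overlap with the recorded SINE was 37.5% for the DUXC and 34.1% for the DUX4 peaks. LINEs held 28.0% of DUX4, 15.9% of DUXC and 5.70% of DUXC-ALT summits. The dog L1 families L1_Canis1 and L1_Cf held 8.03% of DUX4 and 9.37% of DUXC summits and 0 of 561 DUXC-ALT summits, where the limit of 3 counts allows a share of up to 0.535% and the exact interval one of up to 0.655%. The ERVL-MaLR LTRs held 8.50% of DUX4, 6.48% of DUXC and 3.57% of DUXC-ALT summits, and 22.1% (18.7 to 25.8%) of the 561 strongest DUX4 peaks. Any repeat held 47.4%, 47.8% and 65.2% of DUX4, DUXC and DUXC-ALT summits. Counting any overlap with the recorded repeat gave SINE shares of 14.8% for DUX4, 31.0% for DUXC and 5.35% for DUXC-ALT. No chance level was computed for repeats.

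**Figure D3:**
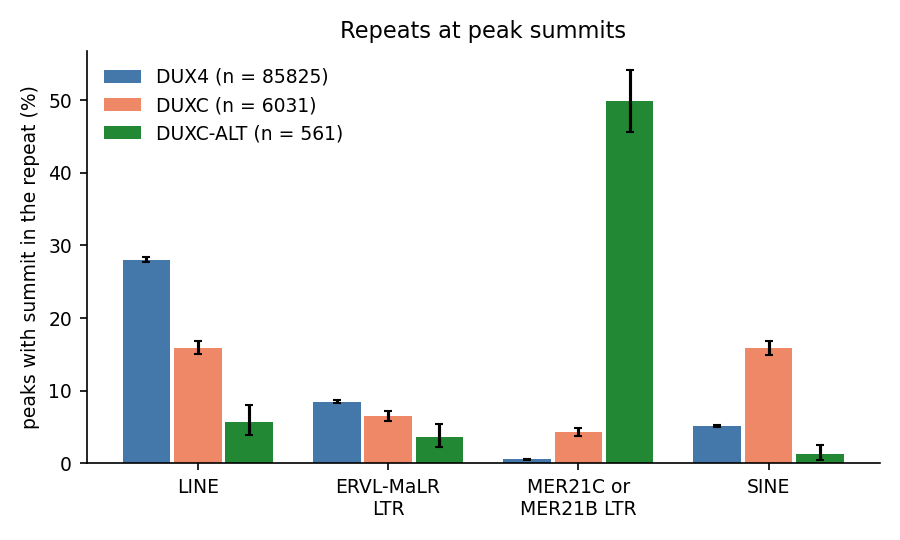
Share of peaks (percent) whose summit lies in each kind of repeat, for the DUX4, DUXC and DUXC-ALT lists, with exact 95% intervals. MER21C or MER21B copies hold 49.9% of DUXC-ALT summits and SINEs 15.9% of DUXC summits.

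Summits of all 3 lists lay in the same part of the MER21C element, an example being intron 23 of EGFR, the epidermal growth factor receptor gene, where a MER21C copy carried peaks in all 3 lists (fold enrichment 7.84 for DUX4, 11.4 for DUXC and 11.8 for DUXC-ALT). In copies of 650 to 850 bp, the median summit lay 270 bp from the 5′ end for DUX4 (208 summits), 275 bp for DUXC (118) and 275 bp for DUXC-ALT (139). The interquartile ranges were 82.75, 68.75 and 60 bp, below the lowest of the random draws along the same copies (276.75, 252.75 and 283 bp).

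**Figure D4:**
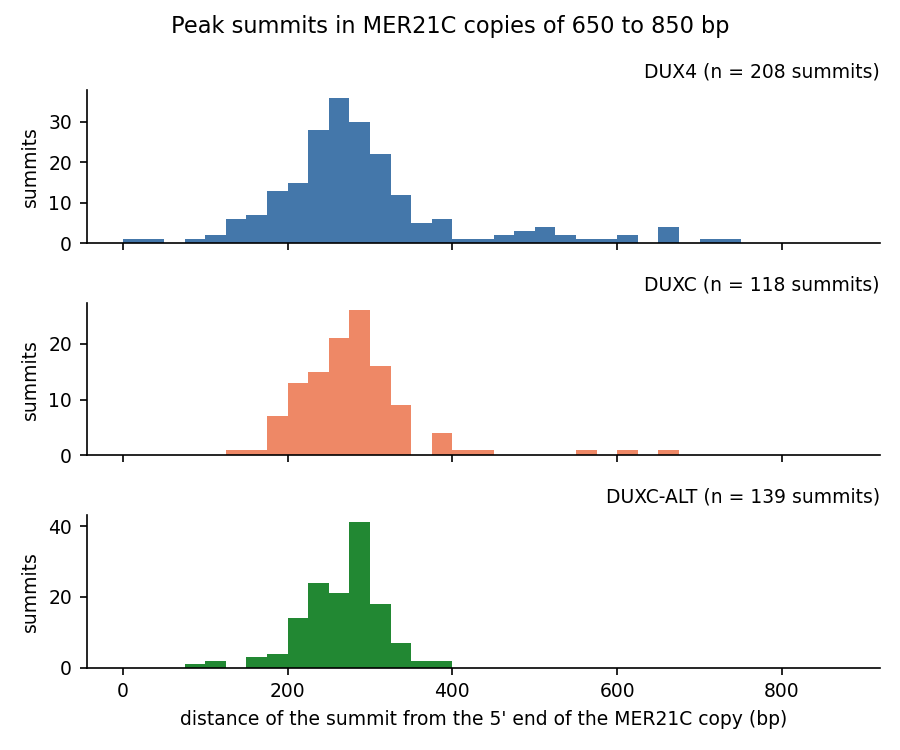
Number of peak summits by distance (bp) from the 5′ end of MER21C copies of 650 to 850 bp, for the DUX4 (208 summits), DUXC (118) and DUXC-ALT (139) lists. The medians are 270, 275 and 275 bp.

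Counts of known DUX4 target and cleavage-stage genes with a nearby DUX4 or DUXC peak lay inside the range of random gene lists. Of 50 such genes listed, 24 were named in the dog reference and 19 in the peak lists. Of these 19, 9 had a DUX4 peak within 5 kb of a TSS (EIF1AX, KDM4E, KLF17, PNMA6A, SLC2A3, SRSF2, WEE1, ZNF296 and ZSCAN4), beside a mean of 7.15 and a range of 3 to 11 in random lists. DUXC had 1, at ZSCAN4, a zinc finger gene of the cleavage-stage embryo: its DUXC peak (chromosome 1, 100396707 to 100396977, 4979 bp upstream of the TSS) had a fold enrichment of 6.25 and overlapped a DUX4 peak of 5.48. At any distance, DUXC peaks were nearest to SLC34A2 (9.37, intron 2), the homeobox gene DUXA (8.27), the histone demethylase gene KDM4E (7.87), the cyclin gene CCNA1 (6.75) and the homeobox gene LEUTX (5.52). Those at DUXA and KDM4E overlapped DUX4 peaks. DUXC-ALT had no peak nearest to any of these genes; random lists had a mean of 0.0821 within 5 kb, too few for a count of 0 to differ from chance.

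The other lists also stayed inside their random ranges. Their totals count only genes named in the peak lists. These were 18 of 40 muscle structural, 21 of 39 homeobox and 17 of 29 myogenic genes listed. For DUX4, 6 of 21 homeobox genes had a peak within 5 kb (among them CRX and GSC), 8 of 26 pluripotency and germline genes (NANOG and DPPA2), and 6 of 17 myogenic regulators, including MYOD1, the master regulator of myogenesis, and MSTN, the myostatin gene. Peaks were also near 9 of 18 muscle structural genes (NEB and DYSF), 7 of 18 fibroblast genes, 5 of 22 neural genes, 6 of 17 liver and gut genes, 7 of 19 innate immune genes, 4 of 15 apoptosis and p53 genes, 12 of 21 nonsense-mediated decay and splicing genes (at the upper end of a random range of 4 to 12) and 15 of 41 housekeeping genes. DUXC peaks were near 1 homeobox gene (RAX, 5.93), 1 muscle structural gene (CKMT2, a mitochondrial creatine kinase, 5.59), 1 fibroblast gene (PDGFRB), 2 innate immune genes (IRF7 and MX1), 3 splicing genes (SF3B1, SRSF3 and TRA2A) and 1 housekeeping gene (EEF2). DUXC had 0 in the pluripotency, myogenic, neural, liver and gut, and apoptosis lists. DUXC-ALT had 0 in all 12 lists, each with a random range that includes 0. Of all 11509 named genes, 37.6%, 5.23% and 0.434% had a DUX4, DUXC or DUXC-ALT peak within 5 kb. With peaks counted in the gene body or within 5 kb of it, 6 of the 21 nonsense-mediated decay and splicing genes had a DUXC peak. This was above the random range of 0 to 5, and 2.01% of random lists had as many. With a distance of 50 kb, 0 of the 17 liver and gut genes had a DUXC peak, below the range of 1 to 7. All 12 lists were counted for each peak list under every setting, and no other count left its range. The splicing list was also at the upper end of its range for DUXC at 50 kb (8 genes, range 1 to 8, 2.66% of random lists). For DUX4 it was so in the gene body or within 5 kb of it (17, range 10 to 17, 8.07%). The main DUXC count of 3 lay inside its range of 0 to 4. These settings share genes and peaks and are not separate observations. Among so many comparisons a few such counts can arise by chance, so neither exception alone sets its list apart.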

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

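Of 229 values under alternative settings, 143 stayed close to the reported value and 86 moved; close means within 1.5 times for counts of peaks or genes, and within the 95% interval for shares, ratios and correlations. Counts and single shares have no sign to reverse, and 0 ratios or correlations whose interval excluded no difference changed direction. The settings chosen only after the result was seen were those without raised local background, without MER21C and MER21B copies, with as many of the strongest DUX4 peaks as DUXC peaks, and with any overlap with the recorded repeat. Where a narrower setting keeps fewer peaks, the lower count follows from its construction; for other values that moved, the cause was not tested. Fold enrichment of at least 10 kept 19870 DUX4, 766 DUXC and 102 DUXC-ALT peaks.

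The share of DUXC peaks overlapping DUX4 was 52.5% with 50% of both peaks, 49.6% with summits within 100 bp, 53.003% at fold enrichment of at least 10, 8.20% with equal numbers of the strongest peaks and 15.8% with the DUX4 list as long as the DUXC list. The share of DUX4 peaks overlapping DUXC was 3.69%, 3.49%, 2.04%, 8.20% and 15.8% under the same settings, 3.73% at q under 1e-05 and 3.73% without raised local background. For DUXC-ALT in DUX4 the values were 8.38% with 50% of both peaks, 4.90% at fold enrichment of at least 10, 0.178% with equal numbers and 0.535% with the shorter DUX4 list. For DUXC-ALT in DUXC they were 10.3% with 50% of both peaks, 8.82% at fold enrichment of at least 10 and 4.63% with equal numbers. The median DUXC-ALT peak (141 bp) is shorter than 50% of the median DUX4 peak (309 bp), so the 50% setting loses pairs by its construction, as a shorter list does. Random shifts of 10 to 100 kb gave 24.3 times chance for DUXC in DUX4, 24.4 for DUX4 in DUXC and 156 for DUXC-ALT in DUXC.

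With −log10 q as the strength, the ratio of shared to unshared medians was 1.14 for DUXC and 2.02 for DUX4, and rho of DUXC with DUX4 was 0.219; with summits within 100 bp the DUXC ratio was 1.11. TSS shares of DUX4, DUXC and DUXC-ALT were 2.27%, 4.66% and 3.03% within 1 kb and 63.3%, 71.1% and 70.9% within 50 kb; the 561 strongest peaks gave 12.8% for DUX4 and 19.4% for DUXC within 5 kb.

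With 50% of the peak in the repeat, any repeat held 43.3% of DUX4 and 42.2% of DUXC peaks, and SINEs 3.50% and 11.97%. Among the 561 strongest peaks, any repeat held 44.9% and 41.9%, MER21C or MER21B 0.713% and 4.99%, and SINEs 2.85% and 21.7%. The any-repeat share, lower in DUX4 than in DUXC as reported (47.4% and 47.8%, overlapping intervals), was thus higher in DUX4 under both settings. Any overlap gave 72.5%, 75.6% and 76.6% for any repeat and 14.8%, 31.0% and 5.35% for SINEs in DUX4, DUXC and DUXC-ALT. The MER21C or MER21B share of DUXC-ALT stayed between 49.9% and 50.2% under all 4 alternatives run for it. Of the 19 DUX4 target genes, 19 had a DUX4 peak with a TSS within 50 kb (random mean 17.98, range 16 to 19). These 19 were counted only because some peak list assigned them a peak, so a count near 19 was almost fixed in advance. A DUXC peak lay within 50 kb of the TSS of 5 of them (random mean 3.43, range 1 to 7), and in the gene body or within 5 kb of it for 3. Counting peaks in the gene body or within 5 kb of it put 1 list (nonsense-mediated decay and splicing) above the random range for DUXC. A distance of 50 kb put 1 list (liver and gut) below it. Every gene list was counted for each peak list under every setting, so a few counts outside their ranges can arise by chance.

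The 5 alternatives foreseen for motif content were not run, and equal numbers give no new value for DUXC-ALT alone, the shortest list. No paired analysis was possible because every group has 1 library and no result comes from a fitted test. The unknown read depth limits what the absence of a peak can show.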

Other observations

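All tests of explanations in this part, and the genes and repeat families named in it, were chosen only after the result was seen. DUX4 summits also lay in a narrower range than random positions in further LTRs. In MLT1D copies of 400 to 550 bp, the median DUX4 summit lay 108 bp from the 5′ end (1310 summits, interquartile range 50 bp, lowest of the random draws 211.75 bp). In MLT1A0 copies of 300 to 400 bp it lay at 92 bp (701 summits, 38 bp against 151 bp). The fewer DUXC summits had a range of 70.5 bp in MLT1D (23 summits, lowest random draw 81 bp) and of 70 bp in MLT1A0 (24 summits, 67.25 bp), the latter not narrower than chance. An MLT1D copy 11731 bp upstream of MYOD1 carried a DUX4 peak of fold enrichment 23.3 (chromosome 21, 40245125 to 40245579) and no DUXC or DUXC-ALT peak. MLT1D held 1815 DUX4, 39 DUXC and 1 DUXC-ALT summits.

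Genes named as homologs of USP17L3, a family of deubiquitinases, had 15 DUX4 peaks, 12 DUXC peaks and 1 DUXC-ALT peak over 5 Ensembl genes, and 10 of the DUXC peaks overlapped a DUX4 peak. DUXC peaks lay within 1 kb of a TSS at 3 of them, with fold enrichments of 9.63, 16.3 and 8.86. The copies are paralogs, and reads can be split between them. Among splicing genes, DUXC and DUX4 peaks overlapped near TRA2A (12.03 and 15.8), SRSF3 (12.6 and 18.4) and SF3B1 (9.85 and 15.4). Promoters with a DUXC peak that overlapped no DUX4 peak included SERPINF1 (14.4) and NFIC (10.4), and FYN, a Src family kinase gene, had both (15.9 and 22.8). Chromosome 24 held 4.33% of DUXC peaks, 1.93% of DUX4 peaks and 2.14% of DUXC-ALT peaks. Satellite repeats were recorded at 48 DUXC peaks, with a median fold enrichment of 1.55; 100% of them had raised local background (median 148.5, against 1.25 over all DUXC peaks).

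MER21C and MER21B copies held a far larger share of the DUXC-ALT list (280 summits) than of the DUX4 list (439) or the DUXC list (258), though not a larger number than in DUX4. Reads shared between repeat copies might also place peaks in the abundant L1_Canis1, L1_Cf and SINEC_Cf families. These held 0 DUXC-ALT summits, where 3 counts would be 0.535% and the exact interval reaches 0.655%, against 8.59% of DUX4 summits. The control and filters of each list are unknown, and the likeness of MER21C and MER21B copies was not measured. The test therefore cannot decide on reads shared between those copies. A short list of strong peaks would show in the DUXC list too, but as many of the strongest DUXC peaks had a share of 4.99% (3.34 to 7.13%). The narrow summit positions (interquartile range 60 bp, lowest random draw 283 bp) are consistent with a fixed site inside the element. A larger share of DUXC-ALT binding at this site may remain as a hypothesis. All 3 lists have summits in this part of the element, but binding by each factor was not separated from shared reads. The polyclonal line, which differed along with the factor, stays open.

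A large share of DUXC peaks had no DUX4 peak, although the DUX4 list was longer. Weak DUXC calls cannot be told apart from separate sites: overlap rose from 45.1% in the weakest to 69.0% (66.3 to 71.6%) in the strongest of 5 equal groups, as weak calls would give, and no measured level shows how high it should go. Raised local background was found at 10.4% (9.28 to 11.6%) of the DUXC peaks without DUX4 and at 6.69% of the others, so it could account for only a small part. MER21C or MER21B copies were overlapped by 6.55% (5.64 to 7.56%) of the DUXC peaks without DUX4, against 2.65% of the others. Binding at such copies would likewise leave most of them. DUX4 sites below the calling threshold, the separate clones and a difference between the factors stay open and were not tested.

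DUXC summits lay in SINE copies more often than DUX4 summits, but at sites shared by both lists the gap of 20.0% against 10.8% by summit was one of 37.5% against 34.1% by any overlap. A short list of strong peaks would give a like share in the strongest DUX4 peaks, where as many gave 4.58% (4.06 to 5.13%) against 15.9% in DUXC. Reads shared between copies cannot be told apart from binding: the L1_Canis1 and L1_Cf share fell from 15.3% in the weakest to 2.74% in the strongest of 5 equal groups of DUXC peaks, but the DUXC to DUX4 ratio was 13.8 in SINEC_Cf and 0.792 in the older MIR family. A fixed site inside the SINE was not resolved, with an interquartile range of 86 bp against a lowest random draw of 70.75 bp and 1 of 4 families narrower than chance, while DUX4 summits were spread wider than chance (124 bp, highest draw 102 bp). A difference between the factors is a possible explanation that was not separated from the clones.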
